A study of Physalis pubescens with 5 samples.

How the data were processed

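The samples were floral buds, collected before fertilization, and young fruits, collected after it, from Physalis floridana P106 plants grown with 16 h of light and 8 h of darkness. Per the labels' protocols, total RNA was extracted with TRIzol, about 20 µg was taken per library, and the libraries were sequenced on an Illumina HiSeq 2000; the protocol mentions 5-day-old fruits, in a text that is the same for all samples. Libraries were grouped by organ from their titles, with 2 libraries per organ. A mixed library used for assembly is in the series but was not analysed here. The design text speaks of triplicates, and the labels give 2 libraries per organ.

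Per the file headers, the deposited counts are numbers of uniquely mapped reads per unigene, where a unigene is a transcript assembled from the reads. The total in each header equalled the sum of its column of counts. The deposited RPKM values, per the file headers, are counts scaled by unigene length and library total, and they were recovered from the counts within a relative deviation of 1.1e-08; they were not used further. The deposited coverage, given by the authors as the percentage of each unigene's length reached by reads, was not used further either. The assembler, aligner and counting program are not given in the sources used here. Each file lists only unigenes with at least 1 count, so a unigene missing from a file was taken as 0. The files listed 115652 unigenes for fruit replicate 1, 104421 for fruit replicate 2, 119786 for floral bud replicate 1 and 103959 for floral bud replicate 2, of 133571 in all, and 86081 were in all 4. Reads of near-identical unigenes could have been split or dropped by the authors' counting of unique reads, so levels of unigenes that share a description are uncertain. No reference genome was used here, and unigenes have no positions.

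Gene names are the deposited descriptions of each unigene's hit in the NCBI nr protein database. The files of replicate 2 carry a further column of pathway terms and another set of descriptions than those of replicate 1. Replicates 1 of both organs are called the first round and replicates 2 the second. The description of the second round was used where it gave one, and that of the first round otherwise; 78.9% of the tested unigenes had a description. The tested and untested unigenes together were 150 to 5370 bases long, and the tested ones had a median of 495 bases.

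Counts were tested with edgeR 4.0.16 in R 4.3.3: unigenes were kept by filterByExpr with the organ as the group, which left 59858, libraries were scaled by TMM factors (1.08 and 0.918 for fruit replicates 1 and 2, 1.04 and 0.964 for floral bud replicates 1 and 2), and glmQLFit and glmQLFTest compared fruit with floral bud with no covariate and 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested unigenes, with a threshold of 0.05, and tests were two-sided. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. CPM values use the library totals without TMM factors. Log2 CPM values used for correlations, principal components and changes within rounds had TMM factors and a prior count of 2. An exact permutation of 2 against 2 libraries cannot give a two-sided p under 0.333, so no such test was run.

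The 26 gene lists were keyword patterns on the descriptions, fixed before the data were examined. Each list of at least 5 tested members was tested with camera of limma 3.58.1, with a preset correlation of 0.01, and adjusted by Benjamini-Hochberg over the 26 lists. Camera with an estimated correlation and fry were run beside it, and with 2 residual degrees of freedom both have little power. The ethylene pattern also takes in descriptions with methylene, and the defence pattern takes in methionine through the stem of thionin; both were kept as written. The vascular pattern also includes the term wall-associated, and the gibberellin pattern the term scarecrow-like, which are broader than the names of these lists. Within each round, with 1 library per organ, the median log2 change of a list was set among those of 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries.

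The rule for named unigenes was also fixed before the data were examined. It took the 5 called unigenes with the largest change in each direction among described unigenes, and from each list the called member with the smallest p in each direction or, where none was called, the member with the highest mean CPM. Since edgeR called none, the rule named 26 unigenes, 1 per list. Every other unigene in the text was chosen after its values were seen.

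The edgeR step was tested on simulated data with 200 changed unigenes among 59858, drawn at the real means and library sizes, 50 at each of the folds 4, 16, 64 and 256. The changed unigenes were taken from those with a mean of more than 50 counts, and all unigenes shared 1 dispersion. For the comparison of fruit with floral bud at a dispersion of 0.28, 2, 40, 49 and 50 of 50 were called at these folds, with 3 false calls. At a dispersion of 0.12, 26, 50, 50 and 50 were called, with 9 false calls, and at 0.05, 48, 50, 50 and 50, with 17 false calls. The dispersion fitted to the data was 0.283, and 0.118 and 0.121 when fruit replicate 1 or fruit replicate 2 was left out.

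Alternatives fixed before the data were examined were DESeq2 1.42.0 with its size factors, 3 other scalings, other filters on low counts, unigenes listed in all 4 files, a test against a 1.5-fold change, a robust fit, the replicate number as a block, leaving out each library in turn, 1 unigene per description in the lists, and other count minimums for unigenes found in 1 organ. Corrected ethylene and defence lists, the first round's descriptions, and the comparison of changes across rounds with its settings were added after seeing the data. Intervals of shares are exact binomial 95% intervals, and bootstrap intervals used 2000 resamples. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.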

Results

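RNA was sequenced from floral buds, collected before fertilization, and from young fruits, collected after it, of Physalis floridana P106, a nightshade whose labelled organism is Physalis pubescens. The plants grew in a glasshouse with 16 h of light and 8 h of darkness. Each organ was represented by 2 libraries, called replicates 1 and 2 in the labels, although the design text speaks of triplicates; a further sample, RNA of mixed organs used for transcript assembly, was not analysed here. Reads had been counted on unigenes, the transcripts assembled from the reads themselves, with lengths of 150 to 5370 bases. The total counts were 9002212 in fruit replicate 1, 8240033 in fruit replicate 2, 8645903 in floral bud replicate 1 and 8375164 in floral bud replicate 2. One count was worth 0.111 to 0.121 CPM, the count scaled to the library total, and the floor of 3 counts lay at 0.333 to 0.364 CPM. The 10 most abundant unigenes took 2.65% of the counts in fruit replicate 1 (exact 95% interval 2.64 to 2.66), 3.48% in fruit replicate 2 (3.47 to 3.49), 2.45% in floral bud replicate 1 (2.44 to 2.46) and 3.15% in floral bud replicate 2 (3.14 to 3.16). No molecular identifiers are described for the reads, so intervals and floors cover counting error only. Nothing in the labels says that the libraries came from separate plants, so p-values measure only the spread between these samples, which may be technical.

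The comparison of fruit with floral bud asks which transcripts differ across the transition from flower to fruit. A vicilin-like transcript (Unigene53698_P106), a relative of seed storage globulins, was at 2959 ± 124 CPM in buds (SD, n = 2) and at 4.11 CPM and 205 CPM in fruit replicates 1 and 2. A glycosyltransferase transcript (Unigene54480_P106) stood at 19.1 ± 4.14 CPM in buds and at 143 CPM and 64.7 CPM in the same fruits. For many other transcripts fruit replicate 1 lay far from the buds and fruit replicate 2 much nearer to them. A transcript for a LAT52-like protein (Unigene54708_P106), a relative of a pollen protein of tomato, was at 639 ± 54.9 CPM in buds (SD, n = 2), 0.67 CPM in fruit replicate 1 and 865 CPM in fruit replicate 2. An alpha-L-fucosidase transcript (Unigene54055_P106) was at 3726 CPM in fruit replicate 1, 33.7 CPM in fruit replicate 2, and 46.2 CPM and 39.0 CPM in the buds. The glycosyltransferase, LAT52-like and alpha-L-fucosidase transcripts were chosen after their values were seen.

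The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 59858 unigenes higher and 0 lower in fruit at an adjusted p under 0.05. At an unadjusted p under 0.05, 305 unigenes were higher and 666 lower. DESeq2 called 30 higher and 128 lower over the 61061 unigenes that it tested. In 7 of its 30 higher calls fruit replicate 1 stood at 32.2 to 74.3 CPM and each other library at 0.36 CPM or less, so these rest on 1 library. So do 2 of the 128 lower calls, seen in floral bud replicate 1 at up to 72.9 CPM and in the others at 0.48 CPM or less. These calls on 1 library were for unigenes that edgeR's filter had left out. Without fruit replicate 2, edgeR called 1546 higher and 4135 lower, and without fruit replicate 1 it called 925 higher and 300 lower. In each of these fits the lone fruit library was assumed to vary like the buds, and both fits share the bud libraries. Camera's calls below with 1 library left out carry the same limit and used the preset correlation only. That preset of 0.01 treats members of a list as nearly independent, which makes p-values too small where members vary together. Over all libraries, the estimated correlation was 0.363 for pollen and anther, 0.242 for photosynthesis and 0.131 for pectin modification. In simulations with the observed dispersion of 0.28 and 2 libraries per organ, edgeR recovered 2 of 50 unigenes changed 4-fold, 40 of 50 changed 16-fold, 49 of 50 changed 64-fold and 50 of 50 changed 256-fold. The changed unigenes had a mean of more than 50 counts, all unigenes shared 1 dispersion, and no library was made to deviate. Recovery in these data, where the fruits differed widely, may therefore be lower.

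The 2 fruit libraries differed from each other more than either differed from the bud library that shares its replicate number. Across the 59858 unigenes, which are not independent replicates, Pearson's r of log2 CPM was 0.645 between the fruits, 0.891 between the buds, 0.768 between fruit and bud replicates 1, and 0.94 between fruit and bud replicates 2. The fruits were more than 2-fold apart for 30.1% of the unigenes, the buds for 16.6%, and fruit and bud replicates 2 for 9.1%. The first principal component held 74.1% of the variance and set fruit replicate 1 apart from the other libraries. Values did not overlap between the organs for 22.7% of the unigenes, where chance gives 33.3%.

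The files of replicate 1 of both organs carry another annotation than those of replicate 2, so fruit and bud were also compared within each such round of files, with 1 library per organ and no test. Fruit replicate 1 against floral bud replicate 1 is the first round, and fruit replicate 2 against floral bud replicate 2 the second. Across unigenes, the log2 changes of the rounds had a Pearson's r of -0.007.

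**Figure D1:**
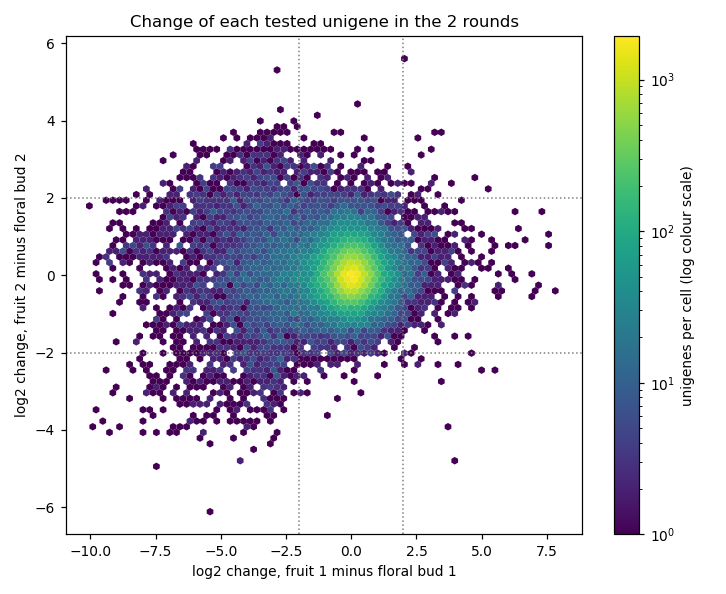
Log2 change of each of the 59858 tested unigenes, fruit minus floral bud, in the first round (horizontal axis) and in the second round (vertical axis), shaded by the number of unigenes per hexagon on a log scale. The changes had a Pearson's r of -0.007 across unigenes, with 395 unigenes at least 4-fold lower in both rounds.

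At least 4-fold lower in the fruit library of both rounds were 395 unigenes, where independent rounds would give 32.3, and at least 4-fold higher were 23, where they would give 6.3. A transcript for a vignain-like cysteine protease (Unigene79387_P106) had 0 counts in fruit replicate 1 and stood at 3.76 CPM in fruit replicate 2, against 67.7 ± 9.17 CPM in buds (SD, n = 2). For an SKP1-like transcript (Unigene36991_P106), a type of ubiquitin ligase subunit, the fruit libraries held 0 counts and 2.43 CPM, and the buds 45.7 and 83.3 CPM. A xylem serine proteinase 1-like transcript (Unigene33019_P106) was at 0.11 CPM, or 1 count, in fruit replicate 1, 7.89 CPM in fruit replicate 2 and 88.8 ± 9.89 CPM in buds. Protein LE25 (Unigene54856_P106), a tomato protein of the late embryogenesis abundant family, stood at 0.56 and 26.8 CPM in the fruits against 147 and 346 CPM in the buds. The counts of 395 and 23 and these unigenes were chosen after the values were seen. Another 395 unigenes were at least 4-fold lower in the first round and 4-fold higher in the second, where independent rounds would give 43.7. For the reverse it was 11, against 4.6. Every combination of directions thus exceeded that number, so an excess alone does not show that the rounds changed alike.

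Some of the calls by DESeq2's Wald test with Benjamini-Hochberg adjustment were for transcripts at similar levels within each organ. A peroxidase transcript (Unigene69146_P106) stood at 27.8 ± 0.67 CPM in fruit and 7.51 ± 0.66 CPM in buds (SD, n = 2; log2 fold change 1.92, DESeq2 adjusted p = 8.91e-05). A transmembrane 9 superfamily member 4-like transcript (Unigene116522_P106) was at 1.06 ± 0.39 CPM in fruit and 15.8 ± 0.19 CPM in buds (log2 fold change -3.88, DESeq2 adjusted p = 5.06e-08). A transcript whose description names a cell death marker (Unigene7560_P106) had 18.0 ± 5.39 CPM in fruit and 1.77 ± 0.54 CPM in buds (DESeq2 adjusted p = 2.6e-05). Primary amine oxidase (Unigene3023_P106) stood at 130.1 ± 30.7 CPM in fruit and 54.0 ± 3.6 CPM in buds (DESeq2 adjusted p = 0.00267). These 4 unigenes were chosen after their values were seen, and each had an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

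**Figure D2:**
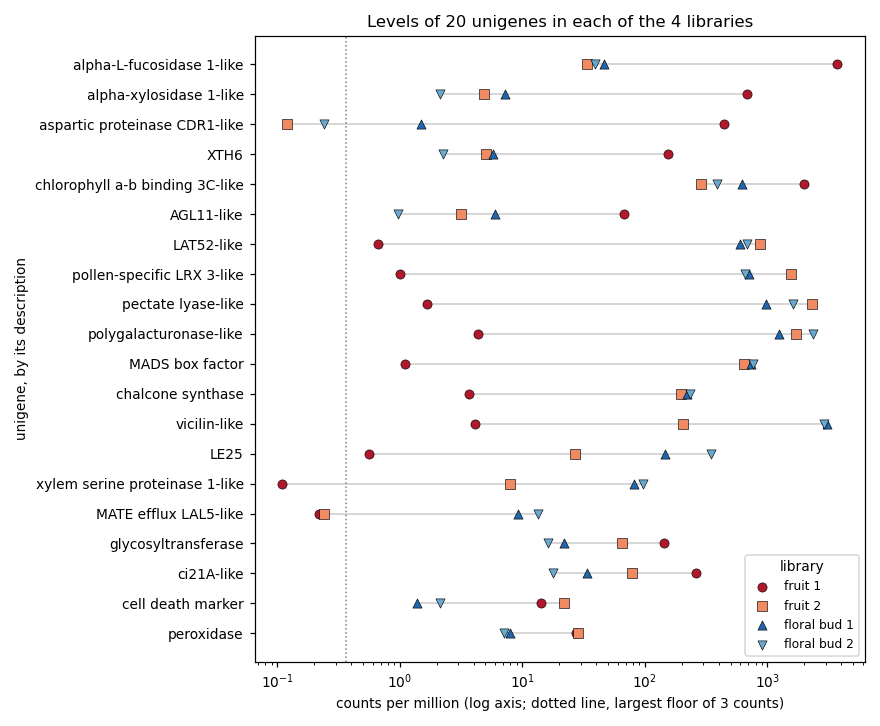
CPM (log axis) of 20 named unigenes in each of the 4 libraries, 1 point per library, with the dotted line at the highest floor of 3 counts. For the LAT52-like transcript the buds lie at 600 and 678 CPM and the fruits at 0.67 and 865 CPM, whereas for the peroxidase the fruits lie at 27.3 and 28.3 CPM.

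Photosynthesis transcripts stood higher in fruit replicate 1 than in the other libraries. The 113 tested members, which serve light capture and carbon fixation, summed to 18292 CPM in fruit replicate 1, 6878 CPM in fruit replicate 2 and 7904 ± 268 CPM in buds (SD, n = 2). The small subunit of ribulose bisphosphate carboxylase (Unigene247_P106), the carbon-fixing enzyme, was at 2479 CPM in fruit replicate 1, 843 CPM in fruit replicate 2 and 942 ± 40.3 CPM in buds. A chlorophyll a-b binding protein of the light-harvesting antenna (Unigene20_P106, chosen after its values were seen) stood at 1997, 286, 622 and 389 CPM in fruit replicates 1 and 2 and bud replicates 1 and 2. The list's median log2 change was 0.35, and camera with a preset correlation called the list up (Benjamini-Hochberg adjusted p = 7.73e-05). It had an adjusted p = 0.8 with an estimated correlation. The median was 0.77 in the first round, above nearly all of 10000 random lists of matched expression, and -0.15 in the second, at percentile 0.1 of such lists. Of single members, edgeR called 21 members higher and 7 lower of 115 without fruit replicate 2, and 1 higher and 0 lower without fruit replicate 1, where camera's call was lost (median -0.08, Benjamini-Hochberg adjusted p = 0.341). Without fruit replicate 2 the median was 0.81.

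Pollen and anther transcripts were lower in fruit replicate 1 and higher in fruit replicate 2 than in buds. The 48 members summed to 868 CPM in fruit replicate 1, 6867 CPM in fruit replicate 2 and 3409 ± 421 CPM in buds (SD, n = 2). A pollen-specific leucine-rich repeat extensin-like transcript (Unigene53919_P106), for a cell wall protein of pollen, was at 1.0, 1567, 707 and 656 CPM in fruit replicates 1 and 2 and bud replicates 1 and 2. An anther-specific TA-29-like transcript (Unigene8857_P106), a relative of a tapetum gene of tobacco, stood at 0.44, 262, 67.8 and 309 CPM in the same order, whereas a pollen-specific C13-like transcript (Unigene53762_P106) was at 432 ± 90.1 CPM in fruit and 392 ± 80.0 CPM in buds; both were chosen after their values were seen. The pollen and anther list was called down by camera with a preset correlation (median log2 change -1.17, Benjamini-Hochberg adjusted p = 0.00157). With an estimated correlation the adjusted p = 0.8. The direction turned with the fruit library, with medians of -2.93 in the first round and 0.34 in the second. By edgeR, 0 members were called higher and 27 lower of 49 without fruit replicate 2, and 14 higher and 1 lower of 50 without fruit replicate 1, where camera called the list up (median 0.47, Benjamini-Hochberg adjusted p = 1.29e-15). The median without fruit replicate 2 was -3.62.

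Transcripts of the pectin modification list were also lowest in sum in fruit replicate 1 and highest in fruit replicate 2. Its 202 members were matched by words for enzymes that modify cell wall pectin, which can also match inhibitors of these enzymes. They summed to 4737 CPM in fruit replicate 1, 17731 CPM in fruit replicate 2 and 10792 ± 2090 CPM in buds (SD, n = 2). A polygalacturonase-like transcript (Unigene53954_P106) was at 4.33 CPM in fruit replicate 1, 1706 CPM in fruit replicate 2, and 1248 and 2364 CPM in the buds. A pectate lyase P59-like transcript (Unigene52640_P106, chosen after its values were seen) stood at 0.22, 562, 135 and 145 CPM in fruit replicates 1 and 2 and bud replicates 1 and 2. The pollen and anther list, beside which these values stand, summed to 868 CPM in fruit replicate 1 and 6867 CPM in fruit replicate 2. The pectin list was called down by camera with a preset correlation (median log2 change -0.28, Benjamini-Hochberg adjusted p = 0.0351). Camera with an estimated correlation gave an adjusted p = 0.8. The median was -0.50 in the first round and 0.15 in the second. Of single members, edgeR called 17 members higher and 67 lower of 211 without fruit replicate 2 but 32 higher and 1 lower of 206 without fruit replicate 1. Without fruit replicate 1, camera's direction for the pectin list was up (median 0.18). That fit leaves 1 fruit library and used the preset correlation only. The list was not called without floral bud replicate 2 (median -0.15). With 1 unigene per description camera did not call the list either (median -0.32, Benjamini-Hochberg adjusted p = 0.0594). It was called down with a median of -0.53 without fruit replicate 2.

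Wall-loosening transcripts, those of expansins, xyloglucan endotransglucosylases and endoglucanases, summed to 3789 and 3515 CPM in fruit replicates 1 and 2 and 2664 and 2814 CPM in bud replicates 1 and 2 (108 members). Xyloglucan endotransglucosylase/hydrolase protein 9 (Unigene1147_P106) was at 476 ± 136 CPM in fruit and 362 ± 35.0 CPM in buds. Another family member, XTH6 (Unigene142173_P106), was at 154 CPM in fruit replicate 1, 5.1 CPM in fruit replicate 2 and 4.03 ± 2.49 CPM in buds, whereas an expansin (Unigene5749_P106) stood at 87.3 ± 22.0 CPM in fruit and 133 ± 2.25 CPM in buds; both were chosen after their values were seen. Camera with a preset correlation called the list up (median log2 change 0.26, Benjamini-Hochberg adjusted p = 0.0179). It had an adjusted p = 0.8 with an estimated correlation. The median was 0.36 in the first round and 0.06 in the second. Of single members, edgeR called 26 members higher and 12 lower of 116 without fruit replicate 2, and 5 higher and 0 lower of 111 without fruit replicate 1. Camera's call was lost without fruit replicate 1 (median 0.14, Benjamini-Hochberg adjusted p = 0.115) or floral bud replicate 1 (median 0.29, adjusted p = 0.249), in the latter case with no smaller median.

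Seed and embryo transcripts summed to 1074 ± 497 CPM in fruit and 6262 ± 263 CPM in buds (SD, n = 2; 51 members). Most of the bud level came from vicilin-like unigenes, which share a description and may be fragments or copies that share reads, so their separate levels are uncertain. A late embryogenesis abundant protein 1-like transcript (Unigene28093_P106) stood at 0.33 and 26.2 CPM in the fruits and 166 ± 19.9 CPM in buds, and a 13S globulin transcript (Unigene10389_P106) went the other way in fruit replicate 1, at 94.5 CPM against 13.6 CPM in fruit replicate 2 and 14.2 ± 4.08 CPM in buds; both were chosen after their values were seen. Of the 51 members, 6 were at least 4-fold lower in both rounds. The seed and embryo list was called down by camera with a preset correlation (median log2 change -0.22, Benjamini-Hochberg adjusted p = 0.00838). With an estimated correlation the adjusted p = 0.8. For the vicilin-like Unigene53698_P106 the log2 fold change was -4.70 (SE 1.91) with an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and -9.59 without fruit replicate 2 and -3.73 without fruit replicate 1 (adjusted p = 1.21e-15 and 2.93e-05). Camera's call for the list was lost without floral bud replicate 2 (median 0.02, Benjamini-Hochberg adjusted p = 0.275). It was kept without fruit replicate 1 (median -0.08) and floral bud replicate 1 (-0.37).

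Flavonoid and anthocyanin transcripts summed to 1424 CPM in fruit replicate 1, 2903 CPM in fruit replicate 2 and 3987 ± 232 CPM in buds (SD, n = 2). Flavanone 3beta-hydroxylase (Unigene6756_P106), an early enzyme of flavonoid synthesis, was at 175 and 333 CPM in the fruits and 427 ± 66.8 CPM in buds. Chalcone synthase (Unigene6973_P106, chosen after its values were seen), which makes the first flavonoid skeleton, stood at 3.67 CPM in fruit replicate 1, 199 CPM in fruit replicate 2 and 228 ± 9.96 CPM in buds. Camera with a preset correlation called the list down (median log2 change -0.17, Benjamini-Hochberg adjusted p = 0.00333). Camera with an estimated correlation gave an adjusted p = 0.8. The median was -0.55 in the first round and -0.08 in the second. Of single members, edgeR called 3 members higher and 31 lower of 119 without fruit replicate 2, and 0 higher and 3 lower of 113 without fruit replicate 1. The list's call by camera was lost without fruit replicate 1 (median -0.08, Benjamini-Hochberg adjusted p = 0.0799) or floral bud replicate 1 (median -0.16, adjusted p = 0.122), in the latter case at nearly the same median. It was kept, with larger medians, without fruit replicate 2 (-0.33) or floral bud replicate 2 (-0.385), with 1 unigene per description (-0.51) and with the first round's descriptions (-0.70, chosen after the results were seen).

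Transcripts of the vascular tissue list, whose pattern also includes wall-associated proteins, summed to 489 ± 98 CPM in fruit and 699 ± 123 CPM in buds (SD, n = 2; 30 members). Sieve element occlusion c (Unigene36332_P106), for a phloem protein, was at 104 ± 39.9 CPM in fruit and 112 ± 25.1 CPM in buds. The 4 members at least 4-fold lower in both rounds included 2 for xylem serine proteinase 1-like proteins, which are proteases. They were Unigene33019_P106 and Unigene31496_P106, the latter at 0 counts and 3.03 CPM in the fruits and 36.4 ± 0.82 CPM in buds (chosen after its values were seen). The vascular list was called down by camera with a preset correlation (median log2 change -0.26, Benjamini-Hochberg adjusted p = 0.00416). It had an adjusted p = 0.8 with an estimated correlation. The median was -0.51 in the first round and -0.17 in the second. The list's call was lost without fruit replicate 2 (median -0.24, Benjamini-Hochberg adjusted p = 0.381) or floral bud replicate 1 (median 0.01, adjusted p = 0.224). Without fruit replicate 1 it was kept, with a median of -0.43.

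Transcripts of the gibberellin list, whose pattern also includes scarecrow-like proteins, summed to 3098 ± 496 CPM in fruit and 2376 ± 378 CPM in buds (SD, n = 2; 98 members). Gibberellin 2-beta-dioxygenase 2-like (Unigene54265_P106), of a family that inactivates gibberellins, was at 1296 and 814 CPM in the fruits and 761 and 559 CPM in the buds. A gibberellin 3-beta-dioxygenase transcript (Unigene29420_P106, chosen after its values were seen), of the family that makes active gibberellins, stood at 103 and 47.5 CPM in the fruits and 44.2 and 20.8 CPM in the buds. Camera with a preset correlation called the list up (median log2 change 0.16, Benjamini-Hochberg adjusted p = 0.00158). With an estimated correlation the adjusted p = 0.8. The median was 0.12 in the first round, at percentile 99.0 of 10000 random lists of matched expression, and 0.19 in the second, above nearly all of them. The call was lost without fruit replicate 1 (median 0.19, Benjamini-Hochberg adjusted p = 0.115) and with 1 unigene per description (median 0.08, adjusted p = 0.0594). It was kept without fruit replicate 2 (median 0.265) or floral bud replicate 2 (0.26). With the first round's descriptions, an alternative chosen after the results were seen, the median was -0.075 and the list was not called (adjusted p = 0.554).

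Transcripts for DNA replication and histones summed to 6183 CPM in fruit replicate 1, 4620 CPM in fruit replicate 2 and 4557 ± 120 CPM in buds (SD, n = 2; 217 members). Histone H1 (Unigene53571_P106), the linker histone of chromatin, was at 546 ± 94.9 CPM in fruit and 416 ± 37.4 CPM in buds. Camera with a preset correlation called the list up (median log2 change 0.22, Benjamini-Hochberg adjusted p = 0.000151). Camera with an estimated correlation gave an adjusted p = 0.8. The median was 0.31 in the first round and 0.04 in the second. The list's call was lost without fruit replicate 1 (median -0.07, Benjamini-Hochberg adjusted p = 0.208) or floral bud replicate 2 (median 0.09, adjusted p = 0.115). It was kept without fruit replicate 2 (median 0.46) or floral bud replicate 1 (0.40). The cell cycle list was not called (193 members, median log2 change 0.06, adjusted p = 0.239 by camera with Benjamini-Hochberg adjustment), and its member cell division cycle protein 48 homolog (Unigene27899_P106) stood at 193 ± 1.09 CPM in fruit and 206 ± 16.5 CPM in buds.

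**Figure D3:**
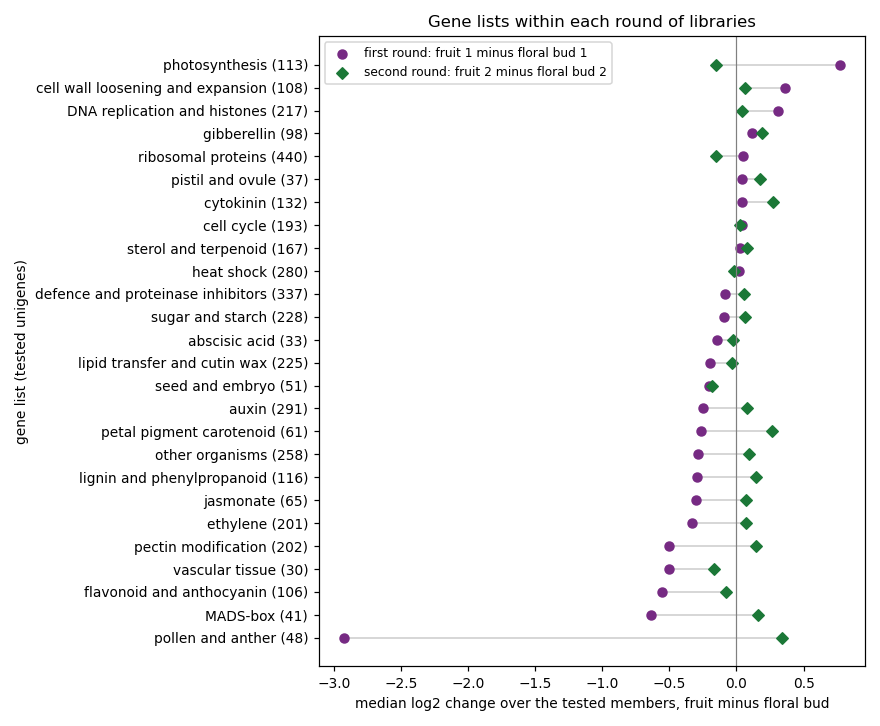
Median log2 change, fruit minus floral bud, over the tested members of each of the 26 gene lists, with the first round as circles and the second round as diamonds. The pollen and anther list had medians of -2.93 and 0.34, and the photosynthesis list 0.77 and -0.15.

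MADS-box transcripts, of a family that includes regulators of floral organ identity, summed to 1447 ± 63 CPM in fruit and 1600 ± 90 CPM in buds (SD, n = 2; 41 members), but single members differed widely between the fruits. A MADS box transcription factor (Unigene586_P106) was at 1.11 CPM in fruit replicate 1, 640 CPM in fruit replicate 2 and 747 ± 17.3 CPM in buds. AGL61-like (Unigene662_P106) stood at 951, 159, 130 and 316 CPM in fruit replicates 1 and 2 and bud replicates 1 and 2, and AGL11-like (Unigene53855_P106) at 68.0, 3.16, 6.01 and 0.96 CPM in the same order. DEFICIENS (Unigene129228_P106), a petal and stamen identity factor, was at 81.3 ± 21.5 CPM in fruit and 111 ± 2.0 CPM in buds. The last 3 unigenes were chosen after their values were seen. The list was not called (median log2 change -0.16, adjusted p = 0.548 by camera with Benjamini-Hochberg adjustment), with medians of -0.64 in the first round and 0.16 in the second.

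Hormone lists other than gibberellin were not called by camera with Benjamini-Hochberg adjustment. Ethylene transcripts (201 members, median log2 change -0.06, adjusted p = 0.948) included a 1-aminocyclopropane-1-carboxylate oxidase (Unigene54240_P106), the last enzyme of ethylene synthesis, at 118 and 2686 CPM in fruit replicates 1 and 2 and 285 and 1527 CPM in bud replicates 1 and 2. Jasmonate transcripts (65 members, median -0.05, adjusted p = 0.298) included lipoxygenase 3 (Unigene55121_P106) at 333 and 1608 CPM in the fruits and 2307 ± 534 CPM in buds. For auxin (291 members, median -0.09, adjusted p = 0.951), IAA9 (Unigene54092_P106) was at 282 ± 65.2 CPM in fruit and 416 ± 66.0 CPM in buds, whereas DESeq2 with Benjamini-Hochberg adjustment called 4 auxin members higher and 0 lower. Of these, Unigene28200_P106, Unigene29148_P106 and Unigene7086_P106 share the description auxin-induced protein 5NG4-like and may be fragments or copies. The other, IAA36 (Unigene74063_P106), was at 26.1 and 2.43 CPM in fruit replicates 1 and 2. Another 5NG4-like unigene (Unigene3932_P106) went the other way, at 0.22 and 2.67 CPM in the fruits and 29.7 ± 12.9 CPM in buds. For cytokinin (132 members, median 0.22, adjusted p = 0.0554), the response regulator-like PRR37-like (Unigene54929_P106), of a family known for the circadian clock, was at 113 ± 59.5 CPM in fruit and 80.8 ± 13.1 CPM in buds. For abscisic acid (33 members, median -0.16, adjusted p = 0.785), the receptor PYL8-like (Unigene128934_P106) was at 60.8 ± 14.95 CPM in fruit and 84.2 ± 36.8 CPM in buds. Leaving out a fruit library turned the ethylene list in opposite directions, to a called median of 0.24 without fruit replicate 1 (Benjamini-Hochberg adjusted p = 0.000625) and of -0.35 without fruit replicate 2 (adjusted p = 0.00137). Camera called the jasmonate list down without fruit replicate 2 (median -0.22, adjusted p = 0.00021).

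The remaining metabolic lists were also not called by camera with Benjamini-Hochberg adjustment. Sugar and starch (228 members, median log2 change -0.04, adjusted p = 0.718) included a beta-fructofuranosidase (Unigene53264_P106), which splits sucrose, at 2.22 CPM in fruit replicate 1, 1308 CPM in fruit replicate 2 and 942 ± 25.3 CPM in buds. Lipid transfer and cutin wax (225 members, median -0.13, adjusted p = 0.513) included ECERIFERUM 1-like (Unigene53140_P106), of wax synthesis, at 523 and 4858 CPM in the fruits and 2384 ± 697 CPM in buds. For lignin and phenylpropanoid (116 members, median -0.20, adjusted p = 0.239), a cinnamyl alcohol dehydrogenase (Unigene29666_P106) was at 410 ± 47.1 CPM in fruit and 346 ± 4.55 CPM in buds. For sterol and terpenoid (167 members, median 0.08, adjusted p = 0.298), a geranylgeranyl diphosphate reductase (Unigene28697_P106) was at 181 ± 48.1 CPM in fruit and 171 ± 15.8 CPM in buds. For petal pigment carotenoid (61 members, median -0.04, adjusted p = 0.951), carotenoid cleavage dioxygenase 1-2 (Unigene6794_P106) was at 141 ± 2.86 CPM in fruit and 167 ± 29.3 CPM in buds. Without fruit replicate 1, camera with Benjamini-Hochberg adjustment called up lipid transfer and cutin wax (median 0.15, adjusted p = 0.00297) and sterol and terpenoid (median 0.18, adjusted p = 0.0154). With 1 unigene per description, lipid transfer and cutin wax was called down (median -0.235, adjusted p = 0.0462). Without fruit replicate 2, it called down lignin and phenylpropanoid (median -0.35, adjusted p = 0.0142) and petal pigment carotenoid (median -0.32, adjusted p = 0.0221).

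Lists for the female organs, stress, translation and other organisms were not called. The pistil and ovule list (37 members, median log2 change 0.14, adjusted p = 0.596 by camera with Benjamini-Hochberg adjustment) summed to 396 ± 3 CPM in fruit and 386 ± 7 CPM in buds (SD, n = 2), with BEL1-related homeotic protein 29 (Unigene53526_P106) at 57.1 ± 4.47 and 44.6 ± 2.75 CPM. The same test gave adjusted p = 0.718 for ribosomal proteins (440 members, median -0.04), with the ubiquitin fusion L40 (Unigene177_P106) at 836 ± 69.4 CPM in fruit and 902 ± 40.7 CPM in buds. It gave adjusted p = 0.596 for heat shock (280 members, median 0.05), with heat shock protein 90-2 (Unigene53339_P106) at 561 ± 85.3 and 827 ± 229 CPM. Defence and proteinase inhibitors (337 members, median 0.00, adjusted p = 0.596) took in methionine synthase (Unigene52543_P106) through a shared word stem only, at 1796 ± 199 and 1801 ± 71.7 CPM. The list of other organisms (258 members, median -0.14, adjusted p = 0.376) matched mostly polyproteins of mobile elements and a starch synthase of the plant (Unigene118793_P106) at 86.1 ± 17.2 CPM in fruit and 147 ± 49.9 CPM in buds. Camera with Benjamini-Hochberg adjustment called ribosomal proteins down without fruit replicate 1 (median -0.18, adjusted p = 0.00112), and other organisms down without floral bud replicate 2 (median -0.60, adjusted p = 3.24e-07). Of the ribosomal protein list, 44 members were at least 4-fold higher in the first round in both organs, and 15 had at least 50 counts in each first-round library and at most 3 in each of the second (both counts chosen after the values were seen).

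DESeq2 called members of 8 lists: 4 higher for auxin, 1 higher for defence, 2 lower for pectin, and 1 lower each for wall loosening, cytokinin, flavonoid, heat shock, and sugar and starch. The pectin calls included Unigene100343_P106, whose description names a complex of pectin methylesterase and its inhibitor protein. The calls for defence and flavonoid each rest on 1 library. The defence unigene (Unigene77930_P106) was at 59.5 CPM in fruit replicate 1 and 0 CPM in the others. The flavonoid unigene (Unigene75031_P106) was at 34 CPM in floral bud replicate 1 and at most 0.48 CPM in the others. In none of the 26 lists did edgeR's quasi-likelihood test call a member over all unigenes, and 0 were called when adjusted over the list alone; each unigene named for its list had an adjusted p of 1 with Benjamini-Hochberg adjustment. None of the 26 lists was called by camera with an estimated correlation or by fry. Fry gave an adjusted p of 0.908 to each of the 9 lists called with the preset correlation. Camera with an estimated correlation gave every list an adjusted p of at least 0.8. With 2 residual degrees of freedom, these lost calls cannot tell correlated members from too few libraries. The gibberellin list lost its call at an estimated correlation of -0.008, below the preset 0.01. With the first round's descriptions, camera with Benjamini-Hochberg adjustment also did not call pollen and anther (median -0.52, adjusted p = 0.0826), vascular tissue (-0.08, 0.776) or seed and embryo (-0.17), nor cell wall loosening (0.26) or DNA replication and histones (0.11), the last 3 with an adjusted p = 0.137. The median and mean differed in sign for cytokinin, defence, heat shock, pistil and ovule, and sterol and terpenoid, and for petal pigment carotenoid both were below 0 while camera's direction was up.

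Of unigenes with at least 10 counts in each library of an organ and 0 in both libraries of the other, 21 were found in buds and 0 in fruit. Among the 21 were a class S F-box transcript (Unigene26955_P106), with 12 and 11 counts in the buds, and PETROSELINUM (Unigene122469_P106), with 13 and 21 counts, both chosen after their values were seen. Counts of 0 in the fruits leave room for levels up to the floors of 0.333 and 0.364 CPM.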

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

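The corrected ethylene and defence lists, the lists from the first round's descriptions and the settings for changes across rounds were tested only after the results were seen; the other alternatives were planned. Under edgeR with other scalings, other filters, unigenes listed in all 4 files, a test against a 1.5-fold change or a robust fit, the count of called unigenes stayed at 0 as in the comparison itself, with 679 to 3427 at an unadjusted p under 0.05. DESeq2 called 158, and the cause was not tested. Leaving out 1 library gave 0 to 5681 calls: 0 without floral bud replicate 1 or 2, 1225 without fruit replicate 1 and 5681 without fruit replicate 2, where the fitted dispersion was 0.46, 0.46, 0.118 and 0.121. These fits have fewer samples, and the lone library is assumed to vary like the other organ. The fit with the replicate number as a replicate block called 0 unigenes, with 1623 at an unadjusted p under 0.05, and camera in that fit called 7 lists. Cytokinin was among them (median log2 change 0.211, Benjamini-Hochberg adjusted p = 0.0198), but pollen and anther (-0.214, 0.334), pectin modification (-0.107, 0.893) and seed and embryo (-0.215, 0.0646) were not. Deviations of same-numbered libraries had a Pearson's r of 0.466 across unigenes. At least 4-fold higher in the first round in both organs were 740 unigenes, where independent organs would give 34.5. For the second round it was 170, against 26.7. These values show differences shared by replicate number, which the main fit did not model. The labels do not say whether the numbers also mark a shared plant or day, and 2 pairs are too few to tell.

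Camera called 9 lists with the preset correlation, 0 with an estimated correlation, 0 by fry, 8 with 1 unigene per description, 9 with the corrected lists and 3 with the first round's descriptions, which match other members; leaving out each library gave 6 to 12. Of 260 list results under an alternative, 206 stayed on their side of the threshold, 8 gained a call, 39 lost it and 7 turned in the direction of the test. Of the 206, 24 had a median of the other sign. Without fruit replicate 1 the median log2 change reversed for DNA replication and histones (-0.068, range over left-out libraries to 0.461), ethylene (0.244, from -0.351), lipid transfer and cutin wax (0.145, from -0.271), pectin modification (0.182, from -0.53), photosynthesis (-0.08, to 0.807) and pollen and anther (0.469, from -3.618). Without fruit replicate 2 camera's direction turned from up to down for petal pigment carotenoid, whose median stayed below 0 (-0.317, range to 0.308). Of 389 results of named unigenes, 378 stayed on their side of the threshold, 17 of them with the other sign, 8 gained a call and 3 reversed. The reversals were each found without fruit replicate 2. There the log2 fold change was -3.09 for Unigene54240_P106 (range to 2.52), -2.31 for Unigene53140_P106 (to 1.14) and -9.49 for Unigene53919_P106 (to 1.32).

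Over all unigenes with at least 1 count, Pearson's r was 0.801 between the fruits, 0.897 between the buds, 0.842 between replicates 1 and 0.94 between replicates 2; these add unigenes of low counts. Unigenes found in 1 organ numbered 65 at a minimum of 5 counts and 2 at a minimum of 20, where the minimum itself sets the count. At least 4-fold lower in both rounds were 404 unigenes with library totals as the scaling, and 1101 were at least 2-fold lower. Planned pseudocounts and filters for files without counts were not run, since the files hold counts. A unigene under 0.333 to 0.364 CPM, the level of 3 counts, could not be told from 0 at this depth.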

Other observations

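The tests reported here were chosen after the results were seen, except that of unigene length, and so were the unigenes. The tests of a label exchange and of the processing round were first run on the 48 members of the pollen and anther list, where they gave 2.93 (bootstrap 95% interval 0.59 to 3.92) and 3.23 (0.25 to 5.54) log2 units. Both intervals reached below the bound of 1 and left the tests undecided, and a set of 327 unigenes was then taken in place of the list. On that set the processing round was first tested by the difference between buds and fruit, 8.33 log2 units (8.14 to 8.45). The fruit part of it is large because the set was chosen on the fruits, so the buds alone were used instead. Single unigenes were found mainly in floral bud replicate 1. A fatty acyl-CoA reductase 2-like transcript (Unigene96272_P106) stood at 82.4 CPM in floral bud replicate 1, 0.84 CPM in floral bud replicate 2, and 0.44 and 0.49 CPM in the fruits. A 4-coumarate--CoA ligase-like 1-like transcript (Unigene143791_P106) was at 57.7 CPM in floral bud replicate 1 and at 0.12 to 0.22 CPM, 1 or 2 counts, in the others. A chalcone synthase-like transcript (Unigene134958_P106) was at 44.9 CPM there and a tetraketide alpha-pyrone reductase 2-like transcript (Unigene138851_P106) at 20.7 CPM, and in the other libraries at most 0.89 and 0.33 CPM. Unigenes at least 8-fold from both other libraries were counted among the buds and fruit replicate 2, above a minimum CPM and with 1 CPM added before the ratio. Of these, 40 were higher and 1 lower in floral bud replicate 1, 28 higher and 16 lower in fruit replicate 2, and 0 stood apart in floral bud replicate 2.

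Single unigenes also stood higher in the second round in both organs. An ACC oxidase transcript (Unigene54439_P106) was at 64.1 and 179 CPM in fruit and bud of the first round and 1396 and 897 CPM in those of the second, and another (Unigene1527_P106) at 22.99 and 108 against 560 and 605 CPM. A non-specific lipid-transfer protein 3-like transcript (Unigene52702_P106) stood at 21.9 and 293 against 2738 and 2439 CPM. At least 4-fold higher in the second round in both organs were 170 unigenes, where independent organs would give 26.7, and 11 of them were among the 201 members of the ethylene list. At least 4-fold higher in the first round were 740, where 34.5 would be given, with 44 in the ribosomal protein list and 16 in the heat shock list. In fruit replicate 2 alone, an inositol oxygenase 5-like transcript (Unigene8529_P106) reached 369 CPM, against 0.22 CPM in fruit replicate 1 and 34.1 ± 4.09 CPM in buds (SD, n = 2).

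The library labelled fruit replicate 2 carried bud-like transcripts: 327 unigenes stood at 100 CPM or more there and at least 20-fold above fruit replicate 1, 10 of them in the pollen and anther list. Their median ratio to fruit replicate 2 was 0.311 in floral bud replicate 1 and 0.515 in floral bud replicate 2. The set was chosen on the fruits, which favours high levels in fruit replicate 2. A mixture of tissue like fruit replicate 1 with bud tissue is argued against by 42 unigenes high in fruit replicate 1 and low in buds, whose median level in fruit replicate 2 was 0.39% of that in fruit replicate 1 (bootstrap 95% interval 0.14 to 0.91), next to 0.73% and 0.38% in the buds. An exchange of labels with a bud library is argued against by the bud libraries, since the lower of their median log2 excesses over fruit replicate 1 was 7.01 (6.77 to 7.25) for the 327 unigenes. The processing round is argued against as the whole cause by the buds, which took no part in choosing them: replicate 1 stood a median of -0.625 log2 units from replicate 2 (-0.708 to -0.558), where a shared effect would need the 20-fold or more of the fruits. A bud library of the same kind as the other 2 stays open. At least 8-fold from both other libraries were 44 unigenes in fruit replicate 2, 41 in floral bud replicate 1 and 0 in floral bud replicate 2. These counts cover only unigenes of at least 20 CPM on the higher side, with 1 CPM added before the ratio. A wrong label involving a sample outside the series also stays open, as do fruits of another age or with floral parts attached. These were not tested.

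Fruit replicate 1 held low-level counts of transcripts abundant in the other 3 libraries. Floral bud replicate 1 held low-level counts of transcripts abundant in fruit replicate 1, which were chosen for low levels in the second round. Carry-over from fruit replicate 2 into fruit replicate 1 is argued against by 108 unigenes of 100 CPM or more in the other 3 libraries and chosen for under 1% of each in fruit replicate 1, over which the log2 ratio to fruit replicate 2 scattered 1.27 times as much as that to floral bud replicate 1 (bootstrap 95% interval 1.13 to 1.43). Carry-over from floral bud replicate 1 into fruit replicate 1 stays open, since the scatter was 0.908 times that against floral bud replicate 2 (0.806 to 1.01), at a median level of 0.224% of floral bud replicate 1. Over 17 unigenes of at least 100 CPM in fruit replicate 1 and at most 0.4 CPM in the second round, the share seen in floral bud replicate 1 had a median of 0.314% and varied 0.92 times as much as counting noise (0.586 to 1.16), which is consistent with carry-over at a constant share between the first-round libraries. True low expression in both first-round libraries was not tested, and no biological explanation that the design names was tested.

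Many unigenes differed between the rounds in both organs. Unigene length is argued against as the cause by a Spearman's rho of 0.065 across 59858 unigenes between length and the difference of the rounds. Of these, 101 unigenes had at least 50 counts in each first-round library and at most 3 in each of the second, summing to 1106 and 1251 CPM in fruit and bud of the first round and 0.1 and 0.0 CPM in the second, while 0 unigenes had the reverse. Among the 70 whose hit names an organism, 0.0% named a nightshade (0 of 70, exact 95% interval up to 5.13%), against 94.6% of 22608 others with as many first-round counts. Hits of the 70 named maize, green algae, spruce and Phytophthora. The second round's descriptions were used first, and the 101 unigenes were nearly absent from that round's files. The 70 and the others may therefore draw on different sets of descriptions, and what this adds to the contrast was not tested. RNA of another organism in the first-round libraries is a candidate explanation, and which organism was not resolved. Of these 101 unigenes, 29 were among the 300 called lower without fruit replicate 1, and 0 among the calls without fruit replicate 2.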
